A study of Homo sapiens with 9 samples.

How the data were processed

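RNA-seq was made from 9 samples of cardiac progenitors derived from the induced pluripotent stem cell line 19-9-11, collected on day 5 of differentiation, with 3 libraries per group. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into stranded libraries that were read from 1 end. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, STAR, HTSeq 0.62 and DESeq2, with the builds hg19 and GRCh37, and the role of each, the annotation, filters and counting options are not given in the sources used here. The design text calls the replicates biological. Nothing more is said of how cultures were separated, so p-values measure the spread between these samples.

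The authors deposited a table of normalized counts (a signal on a linear scale) of 23228 genes, in which each value is a whole number of reads divided by 1 size factor per library. Every value came out whole when multiplied back, to within 0.00000871 reads, so 100% of the values gave whole reads, and the sums of these recovered reads are given as depth, from 10711598 to 13397942 per library. The 10 most abundant genes took between 3.70% and 4.63% of the reads. The authors also deposited 2 tables of their own comparisons, with log2 fold changes and their standard errors on the log2 scale, a test statistic (a score) and p-values with adjusted p-values. Beside the polyI:C table the authors deposited a small typed table, with percent of cells in cell cycle classes. In the polyI:C table the authors' means matched those of the deposited counts, and in the TGFbeta table the deposited counts were higher than the authors' means by a ratio of 1.00 to 1.02, so the scales of the 2 differ slightly. There were 26 gene names turned into dates by a spreadsheet, 19 of them at the minimum mean or above, and these were tested but never named.

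The main test was limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with an intensity trend in the variance, on the 14673 genes with a mean of at least 10 over the 9 libraries. All 9 libraries entered 1 fit with 6 residual degrees of freedom, and p-values were two-sided and Benjamini-Hochberg adjusted within each comparison. Called means an adjusted p under 0.05, and rose and fell are used of called genes. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and log2 changes are given with their SE and levels with their SD. On the recovered reads, edgeR 4.0.16 (quasi-likelihood test) called 360 genes higher and 687 lower with polyI:C and 542 and 459 with TGFbeta. DESeq2 1.42.0 called 378 and 773, and 612 and 546. On simulated data with known changes, limma recovered for polyI:C 56.7% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 97.0% of those changed 4-fold. It made 12 false calls among 14613 genes, or 6.94% of its calls. For TGFbeta it recovered 59.7%, 77.6% and 93.9%, with 12 false calls among 14607 genes, or 7.23% of its calls. The simulated genes varied independently of each other.

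Before the data were examined, 31 gene lists, the tests, the rule for named genes and most alternatives were fixed. The lists cover interferon-stimulated genes, double-stranded RNA sensing, NF-kB targets, cardiac transcription factors, sarcomere genes, cardiac calcium handling and channels, fibroblast and matrix genes, targets of TGF-beta, BMP and Wnt, Notch genes, mesenchymal transition factors, stress responses, metabolism, cell cycle, histones and chromatin enzymes, and markers of other cell types. The list of mitochondrially encoded genes had 0 members in the table, so 30 were tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over 30 lists. Camera called 10 lists for polyI:C, 4 for TGFbeta and 7 for the direct comparison, and 7 for TGFbeta without TGFbeta 1. With an estimated correlation it called 0 in each, where 6, 1 and 4 had an unadjusted p under 0.05. The median, mean and test of a list differed in sign for interferon-stimulated genes, pluripotency genes, primitive streak and mesoderm genes, glycolysis genes and immediate early genes with polyI:C, for epithelial genes, paraxial and intermediate mesoderm genes, endoderm genes, blood cell genes and immediate early genes with TGFbeta and for double-stranded RNA sensing, cardiac transcription factors, mesenchymal transition factors, neuroectoderm and neural crest genes and immediate early genes between treatments. Under TMM or upper-quartile scaling the median changed sign for chromatin genes with polyI:C, for mesenchymal transition, blood and chromatin genes and all genes together with TGFbeta, and for cardiac transcription factors, fatty acid oxidation and immediate early genes between treatments. In edgeR the medians of pluripotency and Notch genes with polyI:C changed sign as well. Fry, which tests whether a list moves one way on balance, called 7, 2 and 13.

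Genes were named by a fixed rule. Per comparison with untreated cells these were the 6 largest rises and falls among called genes with a mean of at least 50 in the higher group and no overlap between libraries, up to 4 called members of each list (or the most abundant member where none was called), and 28 genes named whatever their result. For the direct comparison the 4 largest differences each way and the 28 genes were named. Genes outside the rule are said to have been chosen after their values were seen. Some genes that the rule names are not reported here. Of the 28, those under the minimum mean included TLR3, NKX2-5, POSTN and WT1. Where leaving out 1 library ended or added the call of a gene or list, the libraries are named with the highest or lowest adjusted p. The alternatives were other pseudocounts (0.5 and 5), filters, scalings, tools, a replicate block, fits without a trend or with only the groups compared, stricter thresholds and leaving out each library. Counts with reads thinned to equal depth, and list and overlap counts under other scalings, were added after the data were seen. The reference annotation at hand was of another build than the authors' and no coordinates are given. All per-sample columns of the tables were used.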

Results

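RNA was sequenced from cardiac progenitors that had been differentiated from human induced pluripotent stem cells of the established line 19-9-11. The cells were collected on day 5 of differentiation, in 3 groups of 3 biological replicates. The first group was untreated. The second had received polyI:C, a synthetic double-stranded RNA that cells sense as they sense viral RNA, from day 3 to day 5. The third had received TGFbeta, a growth factor that signals through SMAD proteins, over the same days. The series title calls the polyI:C-treated cells functionally advanced and the TGFbeta-treated cells cardiac fibroblast progenitors, and the comparisons ask how the transcriptome of each differed from untreated progenitors. The reads recovered from the deposited values numbered 10711598, 11413646 and 11836859 in the untreated libraries. They numbered 13204506, 12576904 and 13354074 in the polyI:C libraries, and 12169179, 13397942 and 11864607 in the TGFbeta libraries. The table held 23228 genes, and 14673 with a mean of at least 10 normalized counts were tested.

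The 3 groups lay apart on the first principal component of the transcriptome. On the first principal component, with 50.7% of the variance, the polyI:C libraries scored from -32.0 to -26.5, the untreated libraries from -17.2 to 5.61 and the TGFbeta libraries from 25.6 to 39.1. The second component, with 19.98%, set untreated 1 (-34.5) apart from untreated 2 (-3.05) and untreated 3 (-12.5). Within groups, the correlation of log2 values across genes was between 0.984 and 0.993. Over all pairs the lowest was 0.960, but untreated 2 and untreated 3 correlated with TGFbeta 1 at 0.989 and 0.988. Those 2 values lie above that of untreated 1 with untreated 2 (0.984).

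**Figure D1:**
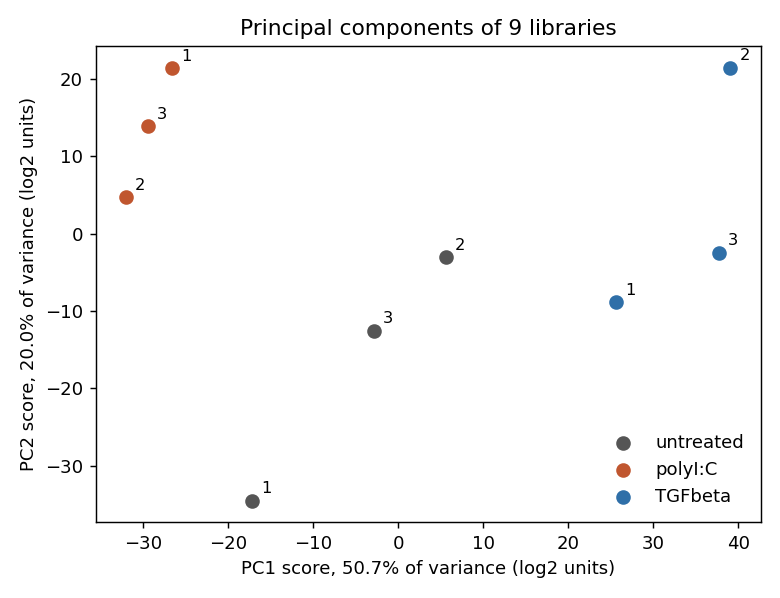
Scores of the 9 libraries on the first 2 principal components of log2 normalized counts of 14673 genes, in log2 units, coloured by group and numbered by replicate. The polyI:C libraries lie at -32.0 to -26.5 on the first component and the TGFbeta libraries at 25.6 to 39.1, with the untreated libraries between them.

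PolyI:C-treated progenitors carried more JAG1 and FOXC2 transcripts and fewer of NODAL, HAND1 and TBX3. JAG1, which encodes a Notch ligand, rose from 1684 ± 167 to 4959.6 ± 453 normalized counts (mean ± SD, n = 3; log2 change 1.56 ± 0.12, SE). The forkhead genes FOXL1, FOXC2 and FOXC1 rose by 2.16 ± 0.27, 2.03 ± 0.32 and 1.02 ± 0.15. NODAL, a TGF-beta family ligand of early patterning, fell from 414 ± 26.9 to 42.0 ± 7.98 (-3.28 ± 0.28, adjusted p = 1.10e-04). HAND1 and TBX3, transcription factors of the early heart, fell by 1.48 and 1.40 on the log2 scale. Some genes of liver and gut endoderm fell too, among them HNF4A (-1.48 ± 0.11) and APOA1 (-2.27 ± 0.32).

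In all, 336 genes rose and 689 fell with polyI:C at an adjusted p under 0.05 in limma, of which 62 and 171 changed by at least 2-fold. The 3 libraries of each group did not overlap for 1024 of these 1025 genes, which selection by a small adjusted p nearly ensures. Over all genes tested the share was 26.9%, against the 10% that chance gives. Among the largest rises were FOXL1, KCNH7 (2.12 ± 0.40), PANX2 (2.05 ± 0.54), HLA-DQA2 (2.04 ± 0.54) and NPY (1.89 ± 0.22), where NPY encodes neuropeptide Y. HLA-DQA2 has a near-identical paralog, so its value is uncertain. The largest falls were TTR (-4.49 ± 1.13), HABP2 (-3.29 ± 0.65), NODAL, GPR55 (-3.10 ± 0.23), DPP4 (-2.97 ± 0.59) and KCNJ16 (-2.94 ± 0.47). Leaving out single libraries ended some of these calls: PANX2 without untreated 2 or 3, polyI:C 1, 2 or 3 (highest adjusted p = 0.154), HLA-DQA2 without untreated 1 or 3, polyI:C 1, 2 or 3, TGFbeta 3 (highest adjusted p = 0.166), TTR without untreated 1 or 3, polyI:C 1 or 3, TGFbeta 3 (highest adjusted p = 0.140), HABP2 without untreated 3, polyI:C 1 or 3 (highest adjusted p = 0.0555) and DPP4 without polyI:C 1 or 3 (highest adjusted p = 0.0556). The rises numbered 167 and 133 without untreated 2 or 3, and 156, 150 and 157 without polyI:C 1, 2 or 3. The falls numbered 403 and 329 without untreated 2 or 3, and 369 and 363 without polyI:C 1 or 3.

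In the authors' deposited table of this comparison, 370 genes were higher and 736 lower at an adjusted p under 0.05. Of the 1105 of them that were tested here, limma called 860 in the same direction and 0 in the other, and all 1105 had the same sign. The log2 values of the authors' deposited table were smaller, with a slope of 0.580 on the limma values across genes, which are not independent replicates.

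The listed interferon-stimulated genes, of a class that cells induce on sensing double-stranded RNA, were not called higher with polyI:C. Of 19 measured, 0 rose in limma and HERC6 fell (-0.79 ± 0.17; 0 higher and 1 lower adjusted over the list alone). At an unadjusted p under 0.05, 3 were higher, and edgeR called 0 higher. IFIT1 stood at 187 ± 54.8 normalized counts against 134 ± 57.9 in untreated cells (log2 change 0.52 ± 0.36, adjusted p = 0.476), and ISG15 at 34.5 ± 22.1 against 32.0 ± 8.85. The upper 95% limit lay under a 2-fold rise for 16 of the 19, and at log2 changes of 1.33 for IFIT1, 1.17 for IFI6 and 1.14 for DDX60. The other 18 fixed members had means under 10 normalized counts. Genes outside the fixed list were not counted here, and IFI16, chosen after its value was seen, rose by 1.13 with polyI:C. IFNB1, the gene of interferon beta, had 1 read over the 3 polyI:C libraries and 0 over the other 6. TLR3, a receptor for polyI:C, was also under the minimum, at 4.04 ± 2.04 against 2.12 ± 0.945 normalized counts. Of 10 genes of double-stranded RNA sensing, MAVS alone was called (-0.20 ± 0.052; 1 adjusted over the list alone). Of 14 NF-kB target genes, 0 were called in limma (0 higher and 1 lower at an unadjusted p under 0.05, 0 and 0 by edgeR), and NFKBIA had a log2 change of -0.43 ± 0.12 (adjusted p = 0.0530). Camera adjusted p-values for these lists were 0.877, 0.7495 and 0.303. With 1 library left out, the call ended for HERC6 without untreated 1 or 2, polyI:C 2 or 3 (highest adjusted p = 0.0746) and MAVS without untreated 1, 2 or 3, polyI:C 1, 2 or 3 (highest adjusted p = 0.138). Leaving out a library added a call of NFKBIA without untreated 1, TGFbeta 1 or 2 (lowest adjusted p = 0.0205). Called rises among interferon-stimulated genes numbered 1 without untreated 1.

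Cardiac regulators moved in both directions with polyI:C. Of 21 genes on the list of cardiac transcription factors, which also holds the growth factor genes FGF8 and FGF10, 3 rose and 7 fell (4 and 7 adjusted over the list alone). The rises included IRX3 and FGF10, both chosen after their values were seen, and besides HAND1 and TBX3 the falls included TBX2 (-1.74 ± 0.33) and GATA4 (-0.59 ± 0.15). ISL1, TBX5 and HAND2 did not pass the test, with log2 changes of -0.18 ± 0.13, 0.57 ± 0.68 and -0.17 ± 0.24. NKX2-5 was under the minimum, with 10.7 ± 2.18 normalized counts in untreated and 7.51 ± 5.18 in polyI:C cells. Of 19 sarcomere genes, 3 fell (3 adjusted over the list alone). The falls were ACTC1, cardiac alpha-actin (-1.92 ± 0.24), MYL4 (-0.68 ± 0.16) and TNNC1 (-0.63 ± 0.16), while TNNT2 (-0.76 ± 0.51), MYH6 (-0.49 ± 0.30) and MYL7 (-0.38 ± 0.32) did not pass. Of 21 cardiac calcium handling and ion channels, 2 rose and 3 fell (2 and 3 adjusted over the list alone). GJA1, a gap junction gene, fell by 0.48 ± 0.077, and HCN4, a pacemaker channel gene, by 0.72 ± 0.15. Camera called none of the 3 lists (adjusted p = 0.524, 0.194 and 0.589). Single libraries decided the call of TBX2 without untreated 3 (highest adjusted p = 0.0516), GATA4 without untreated 1 or 3, polyI:C 1 or 3, TGFbeta 1 or 3 (highest adjusted p = 0.132), MYL4 without untreated 1, 2 or 3, polyI:C 1 or 3 (highest adjusted p = 0.110) and TNNC1 without untreated 2 or 3, polyI:C 1, 2 or 3 (highest adjusted p = 0.145). Calls also ended for HCN4 without untreated 1 or 3, polyI:C 1 (highest adjusted p = 0.0732), IRX3 without polyI:C 3 (highest adjusted p = 0.0625) and FGF10 without untreated 2, polyI:C 1 (highest adjusted p = 0.0534). A call appeared for MYH6 without polyI:C 2 (lowest adjusted p = 0.0326) and the list of sarcomere genes without polyI:C 2 (lowest camera adjusted p = 0.0153). Called falls among cardiac transcription factors numbered 3 without untreated 1, polyI:C 1 or 3 and 2 without untreated 3. Called falls among sarcomere genes numbered 1 without untreated 2 or 3, polyI:C 1 or 3. Called rises among cardiac calcium handling and ion channels numbered 1 without untreated 2, polyI:C 1, TGFbeta 2 and 0 without untreated 1 or 3, polyI:C 2 or 3, TGFbeta 3. Called falls among cardiac calcium handling and ion channels numbered 1 without untreated 3, polyI:C 1.

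Some targets of TGF-beta and BMP signalling fell with polyI:C. Of 23 TGF-beta target genes, 6 fell (8 adjusted over the list alone) (camera adjusted p = 0.00304, and adjusted p = 0.221 with an estimated correlation). The falls included PMEPA1 and SMAD7, both feedback inhibitors of the pathway, at -1.80 ± 0.19 and -0.92 ± 0.078, SKIL at -0.56 ± 0.061 and ADAM19 at -1.12 ± 0.15. Of 16 BMP target genes, 0 rose and 6 fell (2 and 8 adjusted over the list alone) (camera adjusted p = 0.00447, and adjusted p = 0.248 with an estimated correlation), among them SMAD6 (-1.22 ± 0.11), SMAD9 (-0.83 ± 0.11), ID2 (-0.82 ± 0.10) and BMP4 (-0.68 ± 0.10). Of 19 Notch pathway genes, 1 rose (2 adjusted over the list alone), the rise being JAG1 (camera adjusted p = 0.180), while the receptor gene NOTCH1 had a log2 change of 0.34 ± 0.20 and the target HEY1 0.77 ± 0.21 (adjusted p = 0.0550). Of 16 Wnt/beta-catenin target genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone) (camera adjusted p = 0.265). NKD1 and NOTUM, feedback inhibitors of Wnt signalling, fell by 0.98 and 1.20, and DKK1, another Wnt inhibitor, rose by 1.03. Leaving out 1 library ended the call of NOTUM without untreated 3, polyI:C 1 (highest adjusted p = 0.0563) and DKK1 without polyI:C 2 or 3 (highest adjusted p = 0.0617). Calls were gained for HEY1 without untreated 1, TGFbeta 1 or 2 (lowest adjusted p = 0.00997) and the list of Notch pathway genes without untreated 2 (lowest camera adjusted p = 0.0453). Called rises among BMP target genes numbered 1 without untreated 3. Called rises among Notch pathway genes numbered 2 without untreated 1, TGFbeta 1, 2 or 3. Called falls among Wnt/beta-catenin target genes numbered 1 without untreated 3, polyI:C 1.

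Endoderm, endothelial, blood and epithelial lists were lower with polyI:C, and the paraxial and intermediate mesoderm list was higher. Of 16 endoderm genes, 9 fell (11 adjusted over the list alone) (camera adjusted p = 3.83e-06, and adjusted p = 0.221 with an estimated correlation). Besides HNF4A and APOA1 they included HHEX (-1.05 ± 0.10). TTR also differed between untreated libraries, at 1101, 176 and 497 normalized counts. Of 15 endothelial genes, 2 fell (7 adjusted over the list alone) (camera adjusted p = 0.00152, and adjusted p = 0.372 with an estimated correlation), namely SOX7 (-1.22 ± 0.18) and KDR (-0.56 ± 0.13), and PECAM1 had -0.98 ± 0.36. Of 8 blood cell genes, 2 fell (2 adjusted over the list alone) (camera adjusted p = 0.00447, and adjusted p = 0.221 with an estimated correlation), among them TAL1 (-1.40 ± 0.26). Of 17 epithelial genes, 3 fell (3 adjusted over the list alone) (camera adjusted p = 0.00287, and adjusted p = 0.451 with an estimated correlation), led by CLDN7 (-0.91 ± 0.10). Of 7 paraxial and intermediate mesoderm genes, 1 rose (1 adjusted over the list alone) (camera adjusted p = 0.00287, and adjusted p = 0.221 with an estimated correlation), the rise being EYA1 (1.40 ± 0.22), with all 7 above 0. Of 7 epicardial genes, ALDH1A2, which makes retinoic acid, rose by 1.496 ± 0.21 and PODXL fell by 0.76 (1 and 1 adjusted over the list alone; camera adjusted p = 0.877). Of 17 pluripotency genes, NODAL and ZFP42 (-0.32 ± 0.075) fell, and POU5F1 had 0.028 ± 0.31 (4 lower adjusted over the list alone; camera adjusted p = 0.177). Of 13 primitive streak and mesoderm genes, 0 rose and 1 fell (1 and 1 adjusted over the list alone), the fall being APLNR (-0.56 ± 0.072; camera adjusted p = 0.877). Of 12 neuroectoderm and neural crest genes, 1 rose (2 adjusted over the list alone), the rise being TUBB3 (0.47 ± 0.11; camera adjusted p = 0.104). Calls were lost for KDR without untreated 2 or 3, polyI:C 1, 2 or 3 (highest adjusted p = 0.0880), ZFP42 without untreated 1, 2 or 3, polyI:C 1 or 3 (highest adjusted p = 0.114) and TUBB3 without untreated 1 or 2, polyI:C 2 or 3 (highest adjusted p = 0.120). Leaving out a library added a call of the list of pluripotency genes without untreated 1 (lowest camera adjusted p = 0.0142) and the list of neuroectoderm and neural crest genes without untreated 3 (lowest camera adjusted p = 0.0133). Called falls among endoderm genes numbered 5 without untreated 3, polyI:C 1 or 3. Called falls among endothelial genes numbered 5 without TGFbeta 2 and 1 without untreated 2 or 3, polyI:C 1, 2 or 3. Called falls among epithelial genes numbered 1 without polyI:C 3. Called falls among pluripotency genes numbered 1 without untreated 2 or 3, polyI:C 1 or 3. Called rises among primitive streak and mesoderm genes numbered 1 without TGFbeta 2 or 3. Called falls among primitive streak and mesoderm genes numbered 2 without untreated 1.

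Mesenchymal genes split with polyI:C. Of 27 fibroblast and extracellular matrix genes, 1 rose and 4 fell (3 and 4 adjusted over the list alone) (camera adjusted p = 0.458). COL4A1, a basement membrane collagen, fell by 0.83 ± 0.077 and FN1 by 0.42 ± 0.10, while THY1, a surface protein of fibroblasts, rose by 0.60 ± 0.079. COL1A1 (-0.38 ± 0.30), COL3A1 (-0.81 ± 0.47) and DDR2 (-0.52 ± 0.22) did not pass. Of 14 mesenchymal transition factors, 2 rose and 5 fell (4 and 6 adjusted over the list alone), with MSX2 at -1.24 ± 0.10 and CDH2 at -0.66 ± 0.087 beside the rises of FOXC1 and FOXC2 (camera adjusted p = 0.467). Of 13 smooth muscle genes, 1 rose (1 adjusted over the list alone), the rise being TPM2 (0.24 ± 0.048), and ACTA2 had -0.66 ± 0.35 (camera adjusted p = 0.589). TCF21, a marker of cardiac fibroblast precursors, had 0.21 ± 0.17. With 1 library left out, the call ended for FN1 without untreated 1, 2 or 3, polyI:C 1 or 3 (highest adjusted p = 0.128) and TPM2 without untreated 2, polyI:C 3 (highest adjusted p = 0.0595). Called rises among fibroblast and extracellular matrix genes numbered 2 without untreated 1, TGFbeta 1. Called falls among fibroblast and extracellular matrix genes numbered 2 without untreated 1, polyI:C 3 and 1 without untreated 2 or 3, polyI:C 1. Called falls among mesenchymal transition factors numbered 3 without untreated 1 or 3, polyI:C 3 and 2 without polyI:C 1.

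Some cell cycle genes rose by small amounts with polyI:C. Of 24 cell cycle genes, 11 rose (12 adjusted over the list alone), and all 24 had a log2 change above 0 (camera adjusted p = 7.09e-09, and adjusted p = 0.316 with an estimated correlation). The rises included the replication genes PCNA (0.41 ± 0.076), MCM4 (0.34 ± 0.061) and MCM7 (0.33 ± 0.060), while MKI67, a marker of cycling cells, had 0.042 ± 0.094. Of 15 replication-dependent histone genes, 2 rose (5 adjusted over the list alone) (camera adjusted p = 6.20e-05, and adjusted p = 0.496 with an estimated correlation), namely HIST1H3B (0.34 ± 0.089) and HIST1H4E (0.30 ± 0.072), whose near-identical copies make single values uncertain. Of 19 genes of the unfolded protein and integrated stress response, 5 fell (8 adjusted over the list alone) (camera adjusted p = 3.83e-06, and adjusted p = 0.221 with an estimated correlation), among them HSP90B1 (-0.41 ± 0.075), ASNS (-0.63 ± 0.14) and DDIT3 (-0.46 ± 0.11). The remaining lists were not called by camera. Of 36 chromatin-modifying enzymes, 1 rose (0 adjusted over the list alone), the rise being DNMT1 (0.21 ± 0.054; adjusted p = 0.869 for the list). Of 18 p53 target genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone), namely BTG2 (0.29 ± 0.077) and ZMAT3 (-0.41 ± 0.10; 0.877 for the list). Of 17 fatty acid oxidation genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone), namely ACSL1 (0.76 ± 0.20) and PPARGC1A (-1.87 ± 0.24; 0.589 for the list). Of 19 glycolysis genes, 1 fell (1 adjusted over the list alone), the fall being the glucose transporter gene SLC2A3 (-0.85 ± 0.089; 0.877 for the list). Of 10 immediate early genes, 0 were called in limma (1 higher and 1 lower at an unadjusted p under 0.05, 0 and 0 by edgeR; 0.877 for the list), and IER2 had -0.23 ± 0.12. Single libraries decided the call of HIST1H3B without untreated 1, 2 or 3, polyI:C 2 or 3 (highest adjusted p = 0.135), HIST1H4E without untreated 2 or 3, polyI:C 2 or 3 (highest adjusted p = 0.115), ASNS without untreated 2 or 3, polyI:C 1 or 3 (highest adjusted p = 0.0887) and DDIT3 without untreated 1, 2 or 3, polyI:C 2 or 3 (highest adjusted p = 0.110). Calls also ended for DNMT1 without untreated 1, 2 or 3, polyI:C 1, 2 or 3, TGFbeta 1, 2 or 3 (highest adjusted p = 0.152), BTG2 without untreated 1, 2 or 3, polyI:C 2 or 3, TGFbeta 1 or 3 (highest adjusted p = 0.155), ZMAT3 without untreated 1, 2 or 3, polyI:C 1 or 2 (highest adjusted p = 0.130) and ACSL1 without untreated 2 or 3, polyI:C 1, 2 or 3, TGFbeta 3 (highest adjusted p = 0.151). Called rises among cell cycle genes numbered 7 without polyI:C 1 or 3, 6 without untreated 1, 5 without untreated 2, polyI:C 2 and 4 without untreated 3. Called rises among replication-dependent histone genes numbered 0 without untreated 2 or 3, polyI:C 2 or 3. Called falls among genes of the unfolded protein and integrated stress response numbered 3 without untreated 1, 2 without polyI:C 1 and 1 without untreated 2 or 3, polyI:C 3. Called falls among chromatin-modifying enzymes numbered 1 without polyI:C 2. Called rises among glycolysis genes numbered 1 without untreated 1. Called falls among immediate early genes numbered 1 without polyI:C 2.

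**Figure D2:**
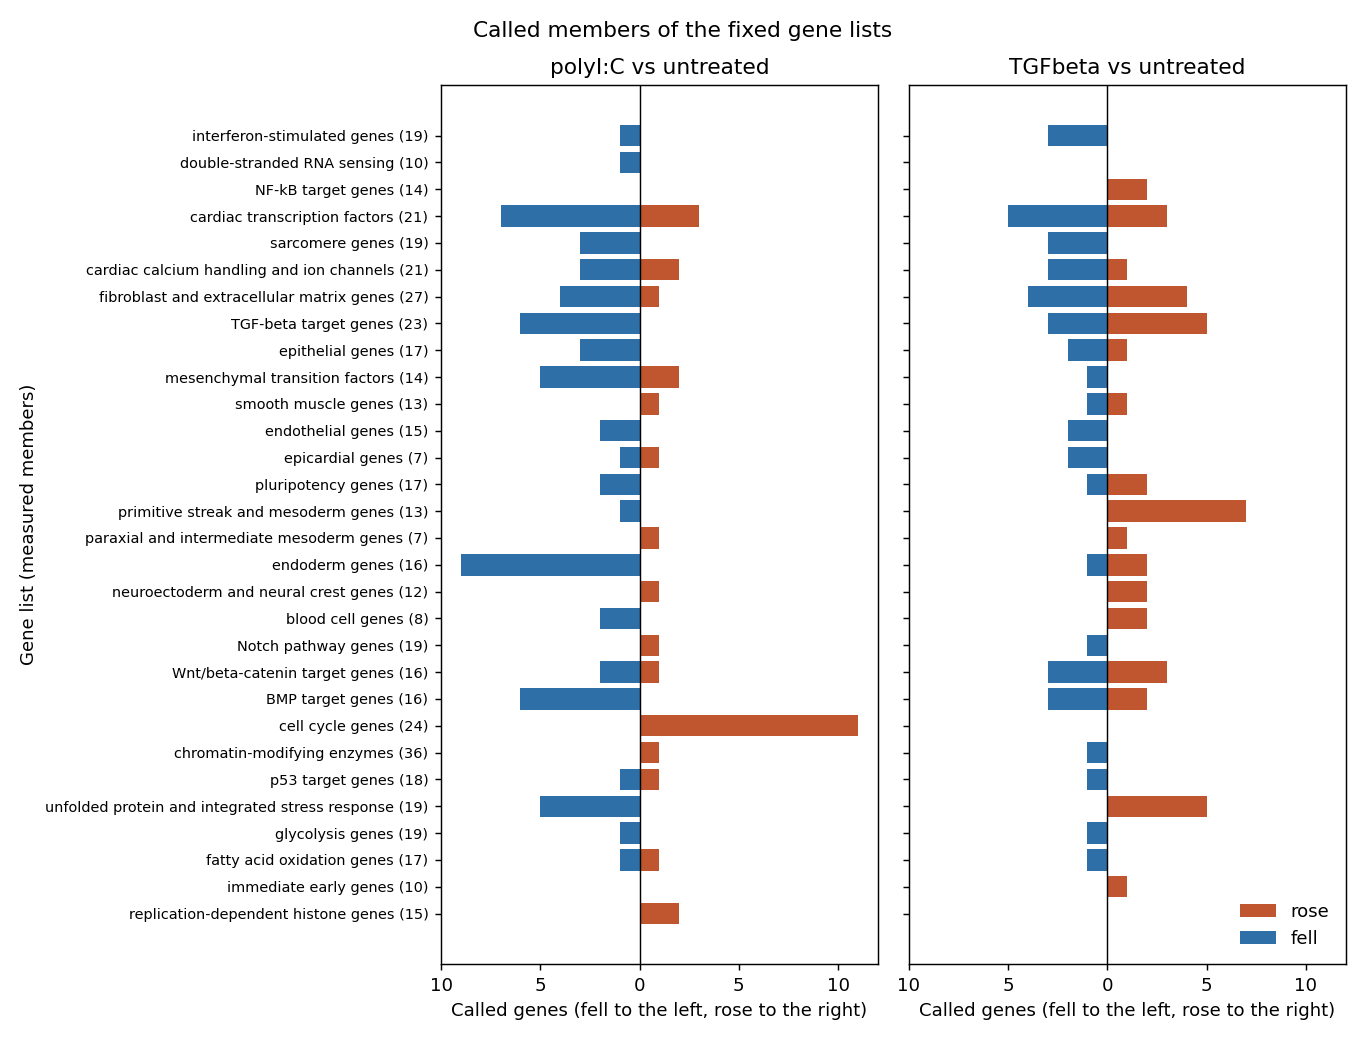
Number of called members (adjusted p under 0.05) of the 30 measured gene lists that rose (right) or fell (left) with polyI:C and with TGFbeta, each against untreated cells, with the number of measured members in brackets. The longest bars are the 11 cell cycle genes that rose and the 9 endoderm genes that fell with polyI:C, followed by the 7 cardiac transcription factors that fell with polyI:C and 7 primitive streak and mesoderm genes that rose with TGFbeta.

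TGFbeta-treated progenitors carried more transcripts of the primitive streak genes CER1, EOMES and MIXL1 and fewer of TBX5, MEF2C and PDGFRA. CER1, a secreted Nodal antagonist, rose from 26.0 ± 10.2 to 496 ± 205 normalized counts (mean ± SD, n = 3; log2 change 4.19 ± 0.36, SE), and LEFTY2, another Nodal antagonist, rose by 3.63 ± 0.63. EOMES and MIXL1, transcription factors of the streak, rose by 2.34 ± 0.36 and 2.08 ± 0.31. TBX5, a regulator of the first heart field, fell from 226 ± 161 to 15.0 ± 18.8 (-4.27 ± 0.68, adjusted p = 0.00570), and MEF2C, a cardiac muscle factor, fell by 1.95 ± 0.22. PDGFRA, a mesenchymal receptor, fell from 19214 ± 3306 to 8805 ± 2253.

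In limma, 433 genes rose and 642 fell with TGFbeta at an adjusted p under 0.05, 137 and 174 of them by at least 2-fold. Rises made up 40.3% of the calls, but 52.6% (534 and 481) with TMM scaling and 54.1% (542 and 459) in edgeR. The libraries of the groups did not overlap for 1070 of the 1075 genes, which their selection nearly ensures, and for 25.7% of all genes tested, against 10% by chance. Among the largest rises were CER1, LEFTY2, FOXP2 (3.05 ± 0.28), JAKMIP1 (2.74 ± 0.52) and SV2B (2.61 ± 0.56). The largest falls were TBX5, PLAT (-2.89 ± 0.62), PLSCR5 (-2.82 ± 0.68), SLC16A12 (-2.73 ± 0.34), NTRK2 (-2.50 ± 0.63) and KCNJ3 (-2.33 ± 0.56). Leaving out 1 library ended the call of SV2B without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.0796), PLAT without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.0815), PLSCR5 without untreated 1 or 3, TGFbeta 3 (highest adjusted p = 0.116), NTRK2 without untreated 1 or 3, polyI:C 3, TGFbeta 2 or 3 (highest adjusted p = 0.138) and KCNJ3 without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.113). PLSCR5 had a log2 change of -1.84 without TGFbeta 2. The rises numbered 201 and 191 without untreated 1 or 3 and 220 and 185 without TGFbeta 2 or 3, and the falls 253, 252, 334 and 301.

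The authors' deposited table for TGFbeta listed 504 genes higher and 435 lower at an adjusted p under 0.05. Limma called 776 of the 935 that were tested here in the same direction and 0 in the other. Here too the log2 values of the authors' deposited table were smaller, with a slope of 0.539 across genes.

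Genes that TGFbeta signalling is known to switch moved in both directions. Of 23 TGF-beta target genes, 5 rose and 3 fell (8 and 6 adjusted over the list alone) (camera adjusted p = 0.0936). PMEPA1 rose by 1.87 ± 0.19, CDKN2B, a cell cycle inhibitor, by 1.65 ± 0.31, LTBP2 by 1.04 ± 0.17 and TGFB1 itself by 0.99 ± 0.16. The other called members, chosen after their values were seen, were SKIL, which rose, and TGFBI, CTGF and IGFBP3, which fell. SMAD7 had 0.23 ± 0.078 (adjusted p = 0.103). Of 16 BMP target genes, 2 rose and 3 fell (5 and 4 adjusted over the list alone) (camera adjusted p = 0.995), with BMP2 at 0.85 ± 0.13 and ID4 at -0.72 ± 0.085. Of 16 Wnt/beta-catenin target genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone) (camera adjusted p = 0.187), with NKD1 at 0.78 ± 0.15 and DKK1 at -1.06 ± 0.21. Of 19 Notch pathway genes, 1 fell (1 adjusted over the list alone), the fall being HEY1 (-1.46 ± 0.21; camera adjusted p = 0.677), beside JAG1 at -0.35 ± 0.12 and NOTCH1 at 0.11 ± 0.20. Calls were lost for SKIL without untreated 1 or 3, polyI:C 1, 2 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.158), TGFBI without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.113) and CTGF without untreated 3 (highest adjusted p = 0.0574). Calls also ended for IGFBP3 without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.110), NKD1 without untreated 1 or 3, TGFbeta 3 (highest adjusted p = 0.0574) and DKK1 without untreated 1 or 3 (highest adjusted p = 0.0621). A call appeared for JAG1 without TGFbeta 2 (lowest adjusted p = 0.0301) and the list of TGF-beta target genes without TGFbeta 2 (lowest camera adjusted p = 0.0374). Called falls among TGF-beta target genes numbered 5 without untreated 2, TGFbeta 1, 1 without untreated 1, TGFbeta 2 or 3 and 0 without untreated 3. Called rises among BMP target genes numbered 1 without untreated 1 or 3, polyI:C 3, TGFbeta 1 or 3. Called falls among BMP target genes numbered 1 without untreated 3, TGFbeta 2 or 3. Called rises among Wnt/beta-catenin target genes numbered 0 without untreated 1 or 3, TGFbeta 3. Called falls among Wnt/beta-catenin target genes numbered 1 without untreated 1 or 3. Called rises among Notch pathway genes numbered 1 without untreated 2. Called falls among Notch pathway genes numbered 2 without TGFbeta 2.

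The list with the most called rises was that of the primitive streak. Of 13 primitive streak and mesoderm genes, 7 rose (8 adjusted over the list alone) (camera adjusted p = 3.55e-07, and adjusted p = 0.438 with an estimated correlation). Besides CER1, EOMES and MIXL1 they included T, the brachyury gene, at 1.44 ± 0.28 and LHX1 at 1.23 ± 0.29. The untreated libraries differed in these genes too, with EOMES at 209, 727 and 378 normalized counts. Of 12 neuroectoderm and neural crest genes, 2 rose (3 adjusted over the list alone) (camera adjusted p = 0.0458, and adjusted p = 0.694 with an estimated correlation), namely PAX6 (1.64 ± 0.30) and OTX2 (0.88 ± 0.16). The list of neuroectoderm and neural crest genes was not called without untreated 1 or 2, TGFbeta 2 (highest camera adjusted p = 0.144). Of 17 pluripotency genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone) (camera adjusted p = 0.289), with L1TD1 at 0.75 ± 0.13, ZFP42 at -0.29 ± 0.075 and POU5F1 at 0.29 ± 0.31. Of 16 endoderm genes, 2 rose and 1 fell (3 and 2 adjusted over the list alone) (camera adjusted p = 0.194), with SOX17 at 0.75 ± 0.17, HNF4A at 0.50 ± 0.11 and FOXA1 at -0.62 ± 0.13. Of 7 paraxial and intermediate mesoderm genes, 1 rose and 0 fell (2 and 1 adjusted over the list alone), the rise being LHX1 (camera adjusted p = 0.553). Of 8 blood cell genes, 2 rose (2 adjusted over the list alone), among them MYB (0.77 ± 0.20; camera adjusted p = 0.196). With 1 library left out, the call ended for LHX1 without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.0958), ZFP42 without untreated 1, 2 or 3, polyI:C 1 or 3, TGFbeta 1, 2 or 3 (highest adjusted p = 0.150) and SOX17 without untreated 3, TGFbeta 2 or 3 (highest adjusted p = 0.0996). Other calls lost were those of HNF4A without untreated 3, TGFbeta 3 (highest adjusted p = 0.0865), FOXA1 without untreated 1 or 3, TGFbeta 2 (highest adjusted p = 0.0747) and MYB without untreated 1 or 3, polyI:C 3, TGFbeta 1, 2 or 3 (highest adjusted p = 0.141). Called rises among primitive streak and mesoderm genes numbered 4 without untreated 1 or 3, TGFbeta 2 or 3. Called rises among endoderm genes numbered 1 without TGFbeta 2 and 0 without untreated 3, TGFbeta 3. Called falls among endoderm genes numbered 2 without TGFbeta 1. Called rises among paraxial and intermediate mesoderm genes numbered 2 without TGFbeta 1. Called rises among blood cell genes numbered 1 without untreated 1 or 3, polyI:C 3, TGFbeta 1, 2 or 3.

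Some heart genes fell and others rose with TGFbeta. Of 21 genes on the list of cardiac transcription factors, which also holds FGF8 and FGF10, 3 rose and 5 fell (3 and 7 adjusted over the list alone) (camera adjusted p = 0.274). FGF10 fell by 0.86 ± 0.12, SMYD1, a muscle methyltransferase gene, by 1.95 ± 0.42 and HAND2 by 0.95 ± 0.24. The 3 rises, chosen after their values were seen, were MESP1, FGF8 and TBX3. HAND1, GATA4 and ISL1 had 0.30 ± 0.14, 0.094 ± 0.15 and -0.20 ± 0.13. Of 19 sarcomere genes, 3 fell (5 adjusted over the list alone) (camera adjusted p = 0.0936), namely UNC45B (-1.49 ± 0.31), TPM1 (-0.74 ± 0.18) and NEBL (-0.60 ± 0.15), while TNNT2 (-1.09 ± 0.51), MYH6 (-0.72 ± 0.30) and MYL7 (-0.85 ± 0.32) did not pass. Of 21 cardiac calcium handling and ion channels, 1 rose and 3 fell (1 and 5 adjusted over the list alone) (camera adjusted p = 0.274), with RYR2 at -1.56 ± 0.35, CACNA1D at -1.43 ± 0.39 and TRDN at 1.55 ± 0.31. The untreated libraries themselves differed in TBX5, at 411, 113 and 154 normalized counts, and in SMYD1, at 448, 179 and 285. Single libraries decided the call of MESP1 without untreated 1 or 3, polyI:C 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.126), FGF8 without TGFbeta 2 (highest adjusted p = 0.0695), TBX3 without untreated 1, 2 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.110), SMYD1 without untreated 1 or 3, TGFbeta 2 (highest adjusted p = 0.0729), HAND2 without untreated 1 or 3, polyI:C 3, TGFbeta 2 or 3 (highest adjusted p = 0.146) and UNC45B without untreated 1 or 3 (highest adjusted p = 0.0640). Calls also ended for TPM1 without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.122), NEBL without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.102), RYR2 without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.0928), CACNA1D without untreated 1 or 3, polyI:C 1, 2 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.175) and TRDN without untreated 3, TGFbeta 3 (highest adjusted p = 0.0637). Calls were gained for MYH6 without polyI:C 2 (lowest adjusted p = 0.0408), MYL7 without TGFbeta 1 (lowest adjusted p = 0.0389) and the list of sarcomere genes without untreated 1, polyI:C 2, TGFbeta 1 (lowest camera adjusted p = 0.0239). Called rises among cardiac transcription factors numbered 1 without untreated 1 or 3, TGFbeta 3 and 0 without TGFbeta 2. Called falls among cardiac transcription factors numbered 3 without untreated 1 or 3, TGFbeta 2. Called falls among sarcomere genes numbered 5 without TGFbeta 1, 1 without TGFbeta 2 or 3 and 0 without untreated 1 or 3. Called falls among cardiac calcium handling and ion channels numbered 5 without TGFbeta 1 and 0 without untreated 1 or 3, TGFbeta 2 or 3.

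Fibroblast genes did not rise as a group. Of 27 fibroblast and extracellular matrix genes, 4 rose and 4 fell (4 and 12 adjusted over the list alone) (camera adjusted p = 0.254). COL4A1 rose by 0.52 ± 0.077, and PDGFRA (-1.15 ± 0.17), S100A4 (-0.80 ± 0.12) and THY1 (-0.54 ± 0.079) fell. The collagen genes COL4A2, COL5A1 and COL5A2 also rose and COL1A2 also fell, and these were chosen after their values were seen. COL1A1 (-0.85 ± 0.30), COL3A1 (-1.13 ± 0.47), FN1 (0.092 ± 0.10), DDR2 (-0.50 ± 0.22), TCF21 (-0.53 ± 0.17) and ACTA2 (-0.72 ± 0.35) did not pass, and POSTN was under the minimum at 8.84 ± 2.12 against 9.54 ± 3.71 normalized counts. Of 7 epicardial genes, 2 fell (7 adjusted over the list alone), and all 7 were below 0 (camera adjusted p = 0.00171, and adjusted p = 0.438 with an estimated correlation). ALDH1A2 fell by 1.32 ± 0.21 and BNC1 by 1.14 ± 0.24, and WT1 was under the minimum at 9.86 ± 2.75. Of 14 mesenchymal transition factors, 0 rose and 1 fell (1 and 3 adjusted over the list alone), the fall being TWIST1 (-0.78 ± 0.18; camera adjusted p = 0.921). Of 13 smooth muscle genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone), namely CNN1 (0.49 ± 0.11) and LMOD1 (-1.27 ± 0.33; camera adjusted p = 0.987). Of 15 endothelial genes, 2 fell (2 adjusted over the list alone), namely TIE1 (-1.05 ± 0.19) and TEK (-0.997 ± 0.23; camera adjusted p = 0.254), and PECAM1 had -0.83 ± 0.36. Of 17 epithelial genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone), with CLDN4 at -0.95 ± 0.15, KRT18 at -0.29 ± 0.069 and CLDN7 at 0.38 ± 0.10 (camera adjusted p = 0.885). Leaving out 1 library ended the call of COL5A1 without untreated 3 (highest adjusted p = 0.0533), COL5A2 without untreated 1, 2 or 3, polyI:C 1, 2 or 3, TGFbeta 1 or 3 (highest adjusted p = 0.162), COL1A2 without untreated 1 or 3, polyI:C 1, 2 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.146), BNC1 without untreated 1, TGFbeta 3 (highest adjusted p = 0.0653) and TWIST1 without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.106). Other calls lost were those of CNN1 without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.0752), LMOD1 without untreated 1 or 3, polyI:C 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.150), TEK without untreated 1 or 3, TGFbeta 3 (highest adjusted p = 0.0915), KRT18 without untreated 1, 2 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.110) and CLDN7 without untreated 1 or 3, polyI:C 1, 2 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.175). Leaving out a library added a call of ACTA2 without TGFbeta 1 (lowest adjusted p = 0.0225), COL1A1 without TGFbeta 1 (lowest adjusted p = 0.00793), COL3A1 without TGFbeta 1 (lowest adjusted p = 0.0250), TCF21 without TGFbeta 1 (lowest adjusted p = 0.0242) and the list of fibroblast and extracellular matrix genes without TGFbeta 1 (lowest camera adjusted p = 0.0305). Called rises among fibroblast and extracellular matrix genes numbered 2 without untreated 3. Called falls among fibroblast and extracellular matrix genes numbered 14 without TGFbeta 1. Called falls among epicardial genes numbered 4 without TGFbeta 1 and 1 without untreated 1, TGFbeta 3. Called falls among mesenchymal transition factors numbered 3 without TGFbeta 1. Called falls among smooth muscle genes numbered 2 without TGFbeta 1. Called rises among endothelial genes numbered 1 without TGFbeta 1. Called falls among endothelial genes numbered 1 without untreated 1 or 3, TGFbeta 3. Called falls among epithelial genes numbered 1 without untreated 2 or 3, TGFbeta 2.

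Some stress response genes rose with TGFbeta, while 0 cell cycle genes were called. Of 19 genes of the unfolded protein and integrated stress response, 5 rose (6 adjusted over the list alone) (camera adjusted p = 3.55e-07, and adjusted p = 0.438 with an estimated correlation), among them ASNS (0.61 ± 0.14), TRIB3 (0.69 ± 0.15) and ATF3 (0.90 ± 0.20). Of 24 cell cycle genes, 0 were called in limma (0 higher and 1 lower at an unadjusted p under 0.05, 0 and 0 by edgeR; camera adjusted p = 0.196), with TOP2A at -0.039 ± 0.084 and MKI67 at 0.18 ± 0.094. Of 15 replication-dependent histone genes, 0 were called (2 higher and 0 lower at an unadjusted p under 0.05, 0 and 0 by edgeR; camera adjusted p = 0.0936), with HIST1H1B at 0.10 ± 0.10. Of 19 interferon-stimulated genes, 3 fell (5 adjusted over the list alone) (camera adjusted p = 0.384), namely IFIT1 (-2.16 ± 0.36), IFIT5 (-0.64 ± 0.11) and IFI6 (-1.41 ± 0.33), and ISG15 had -0.046 ± 0.41. Of 10 genes of double-stranded RNA sensing, 0 were called (0 higher and 0 lower at an unadjusted p under 0.05, 0 and 0 by edgeR; camera adjusted p = 0.539), with ADAR at -0.051 ± 0.058. Of 14 NF-kB target genes, 2 rose (3 adjusted over the list alone) (camera adjusted p = 0.198), namely CCL2 (1.78 ± 0.30) and NFKBIA (0.81 ± 0.12). In the remaining lists, none called by camera, the called genes were ATF3 among 10 immediate early genes, KDM6A (-0.49 ± 0.10) among 36 chromatin-modifying enzymes, SESN1 (-0.29 ± 0.074) among 18 p53 target genes, PFKM (-0.32 ± 0.064) among 19 glycolysis genes and ACSL1 (-0.92 ± 0.20) among 17 fatty acid oxidation genes, and the numbers adjusted over the list alone were 1 in each. Their camera adjusted p-values were 0.271, 0.553, 0.558, 0.170 and 0.195. Calls were lost for ASNS without untreated 1 or 3, TGFbeta 3 (highest adjusted p = 0.0843), TRIB3 without untreated 1 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.0833) and ATF3 without untreated 1, TGFbeta 2 or 3 (highest adjusted p = 0.0915). Calls also ended for IFI6 without untreated 1 or 3, TGFbeta 1, 2 or 3 (highest adjusted p = 0.0973), SESN1 without untreated 1, 2 or 3, polyI:C 1, 2 or 3, TGFbeta 1, 2 or 3 (highest adjusted p = 0.140) and ACSL1 without untreated 1 or 3, TGFbeta 2 (highest adjusted p = 0.0658). A call appeared for the list of cell cycle genes without TGFbeta 1 (lowest camera adjusted p = 0.0305), the list of glycolysis genes without TGFbeta 2 (lowest camera adjusted p = 1.48e-04) and the list of replication-dependent histone genes without TGFbeta 3 (lowest camera adjusted p = 0.00187). Called rises among genes of the unfolded protein and integrated stress response numbered 2 without untreated 3, TGFbeta 2 and 0 without untreated 1, TGFbeta 3. Called rises among interferon-stimulated genes numbered 1 without untreated 2. Called falls among NF-kB target genes numbered 1 without TGFbeta 1. Called falls among glycolysis genes numbered 2 without TGFbeta 2.

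**Figure D3:**
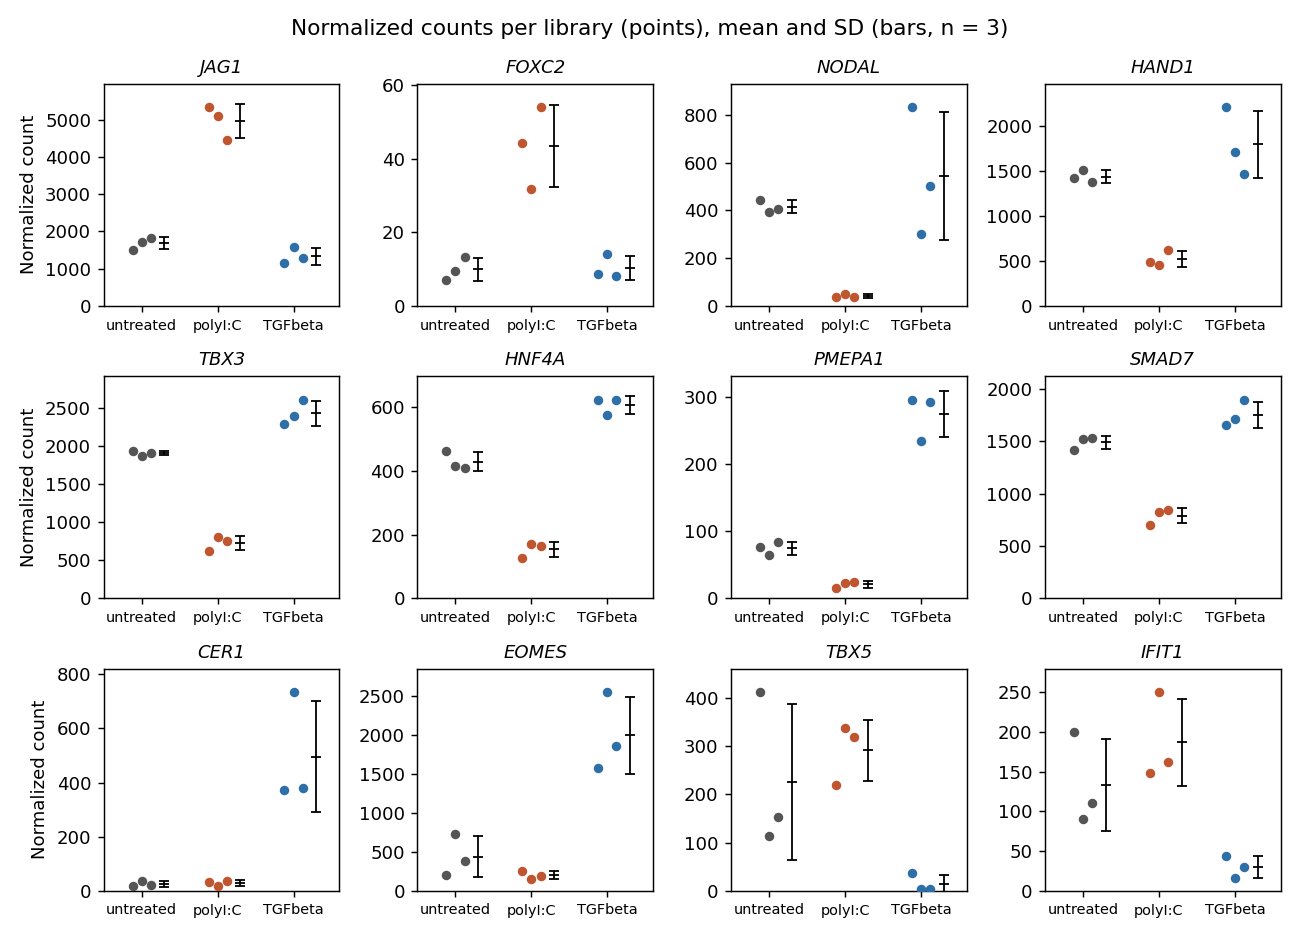
Normalized counts of 12 named genes in each of the 9 libraries (points), with the mean and SD of each group (bars, n = 3, drawn only above 0). NODAL, HAND1, TBX3, HNF4A, PMEPA1 and SMAD7 lie lower in all 3 polyI:C libraries than in any other, and CER1, EOMES and PMEPA1 lie higher in all 3 TGFbeta libraries.

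Set directly against each other, the treatments differed in more genes than either did from untreated cells. HAND1 stood at 1792 ± 374 normalized counts with TGFbeta and 518 ± 89.8 with polyI:C (mean ± SD, n = 3; log2 difference 1.78 ± 0.14, SE), and JAG1 at 1334 ± 226 and 4959.6 ± 453 (-1.90 ± 0.12). Among the largest differences above 0 were those of ADAMTSL2 (4.79 ± 0.34) and TRPA1 (4.42 ± 0.21), and the largest below 0 were those of TBX5 (-4.83 ± 0.68), HLA-DQA2 (-4.01 ± 0.54), FAM5B (-3.90 ± 0.55) and SLC16A12 (-3.84 ± 0.34). Of the genes tracked throughout, SMAD7 (1.15 ± 0.078), GATA4 (0.68 ± 0.15) and FN1 (0.51 ± 0.10) were higher with TGFbeta, and HEY1 (-2.24 ± 0.21), IFIT1 (-2.68 ± 0.36), TCF21 (-0.74 ± 0.17) and HAND2 (-0.78 ± 0.24) were lower. TNNT2, MYH6, MYL7, COL1A1, COL3A1, DDR2, ACTA2, ISL1, ISG15, NOTCH1, PECAM1, POU5F1 and MKI67 did not pass the test of this difference. Calls were gained for COL1A1 without TGFbeta 1 (lowest adjusted p = 0.0196).

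In limma, 1609 genes were higher and 1962 lower with TGFbeta than with polyI:C, and 1926 and 1451 with TMM scaling, so the share of higher calls was 45.1% or 57.0%, and 55.8% in edgeR (1918 and 1520). Camera called 7 of 30 lists. The unfolded protein and integrated stress response was higher (15 of 19 genes higher, 16 adjusted over the list alone; camera adjusted p = 2.11e-09, and adjusted p = 0.184 with an estimated correlation). So were endoderm genes (10 of 16 higher and 1 lower, 10 and 2 adjusted over the list alone; camera adjusted p = 1.69e-04, and adjusted p = 0.184 with an estimated correlation). Primitive streak and mesoderm genes were higher (8 of 13, 8 adjusted over the list alone; camera adjusted p = 2.44e-04, and adjusted p = 0.501 with an estimated correlation), as were TGF-beta target genes (10 higher and 4 lower of 23, 11 and 5 adjusted over the list alone; camera adjusted p = 0.00604, and adjusted p = 0.184 with an estimated correlation). The same held for blood cell genes (4 higher and 1 lower of 8, 6 and 1 adjusted over the list alone; camera adjusted p = 0.00771, and adjusted p = 0.251 with an estimated correlation) and BMP target genes (7 higher and 4 lower of 16, 10 and 4 adjusted over the list alone; camera adjusted p = 0.0456, and adjusted p = 0.490 with an estimated correlation). The list of blood cell genes was not called without TGFbeta 1 (highest camera adjusted p = 0.0636). The list of BMP target genes was not called without untreated 1, 2 or 3, polyI:C 3, TGFbeta 3 (highest camera adjusted p = 0.0646). Cell cycle genes were lower (10 of 24, 10 adjusted over the list alone; camera adjusted p = 0.00270, and adjusted p = 0.665 with an estimated correlation). The call was lost for HAND2 without untreated 3, polyI:C 2 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.136), and the lower genes numbered 1277 without polyI:C 1. Called lower values among endoderm genes numbered 0 without polyI:C 1 or 3, TGFbeta 2. Called lower values among primitive streak and mesoderm genes numbered 1 without TGFbeta 2. Called lower values among TGF-beta target genes numbered 2 without polyI:C 1 or 2, TGFbeta 2 or 3. Called lower values among blood cell genes numbered 0 without polyI:C 1 or 3, TGFbeta 2 or 3.

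Genes that answered both treatments mostly did so in opposite directions. Of 218 genes called in both comparisons with untreated cells, 80 rose with polyI:C and fell with TGFbeta, and 117 did the reverse. Another 3 rose and 18 fell with both. PMEPA1 and COL4A1 fell with polyI:C and rose with TGFbeta, and ALDH1A2 and THY1 did the opposite. Independent lists of these sizes would share 35.0 genes in opposite directions and 40.1 in the same. In 100 simulations all 9 libraries were replaced by gene means plus noise drawn from the residuals of the fit. Both unchanged groups were compared with the same 3 simulated controls. At most 0 genes were called in opposite directions, since shared controls push both responses the same way, and a median of 0 and at most 993 in the same. Across all genes, which are not independent replicates, the log2 changes had a Pearson r of -0.089 against a simulated median of 0.58 (95% of simulations from -0.23 to 0.93, a range that holds the observed r). The covariance was -0.0114 against 0.0142 (-0.00481 to 0.0664). With 3 controls no split leaves 2 libraries on each side, so sharing them may account for part of any excess in the same direction. The opposite calls numbered 107 and 68 without untreated 2 or 3, 119, 129 and 103 without polyI:C 1, 2 or 3, and 121 without TGFbeta 3. Calls in the same direction numbered 6 without untreated 1, 5 without untreated 3, 5 without polyI:C 1, 4 without polyI:C 3, 51 without TGFbeta 1, 13 without TGFbeta 2 and 12 without TGFbeta 3. The correlation turned positive without untreated 2 (r = 0.12) and without untreated 3 (r = 0.0052).

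**Figure D4:**
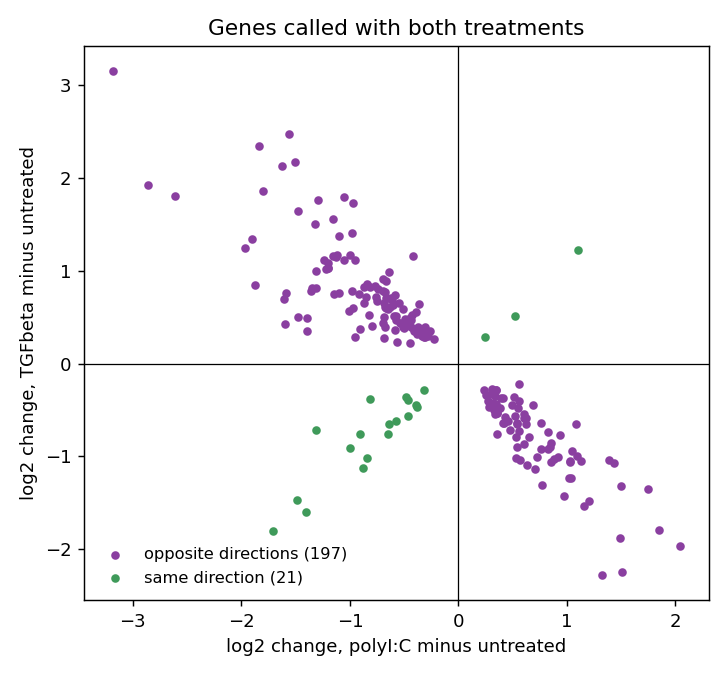
Log2 changes with polyI:C (horizontal) and TGFbeta (vertical), each against untreated cells, of the 218 genes called in both comparisons. The 197 genes with opposite directions fill the upper left and lower right, and 21 lie in the other corners.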

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

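No test was run on these values, which were noticed only after the data were seen. Beside the polyI:C comparison, the authors' deposited table holds a small set of cell cycle percentages that no comparison of the report uses, with no number of cells or replicates. It lists 53.7% of cells in G2/S without polyI:C and 61.3% with it. Higher percentages than in the cells without polyI:C also stand in the authors' deposited table for cells labelled NPY, at 61.9% for the 0.1 uM label and 61.4% for the 1 uM label. PolyI:C together with the additive labelled QNZ stands at 49.5%, and with both QNZ and 0.1 uM NPY at 58.7%. In the libraries, NPY rose with polyI:C from 40.3 ± 8.08 to 153 ± 37.2 normalized counts (mean ± SD, n = 3). Without replicates, none of these percentages can be set against an error.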

How the results depend on the processing

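Equal depth, and list and overlap counts under other scalings, were chosen after the data were seen. Of 226 named gene values, 171 were called and 97 were called whichever library was left out, and no called gene or list among them changed direction. Without a variance trend 61 of the named calls were lost. A replicate block ended 29 and added 2, and a fit of only the groups compared ended 20 and added 2. Counts of called genes fell with stricter settings by construction: at least 2-fold gave 62 up and 171 down with polyI:C, 137 and 174 with TGFbeta, and 441 and 369 between treatments, and an adjusted p under 0.01 gave 89 up and 271 down with polyI:C, 119 and 157 with TGFbeta, and 932 and 908 between treatments. Without a variance trend the counts were 181 and 412 with polyI:C and 201 and 320 with TGFbeta, and a fit of only the groups compared gave 361 falls with TGFbeta; the cause was not tested. Leaving out 1 library, which leaves fewer samples, gave 133 to 371 rises and 329 to 756 falls with polyI:C, 185 to 529 and 252 to 809 with TGFbeta, and 1188 to 1697 and 1277 to 2083 between treatments. Gene lists called ranged from 10 to 11, 3 to 7 and 6 to 10, and 0 in each with an estimated correlation. Genes called in opposite directions ranged from 68 to 213 and in the same from 4 to 51. The correlation of the responses across genes ranged from -0.20 to 0.12, and turned positive without untreated 2 (0.12) and untreated 3 (0.0052). Libraries with the same number did not deviate together throughout (correlations of -0.31 to 0.44, 2 of 9 above 0.1), and 4 of 9 correlated best with their own number. The 2 above 0.1 were untreated with TGFbeta, at 0.32 for number 1 and 0.44 for number 2, against -0.074 for number 3. The numbers thus do not pair all groups, and a pairing of untreated with TGFbeta stays open. A replicate block gave 216 rises and 529 falls with polyI:C and 354 and 509 with TGFbeta. Depth limits low genes: 18 interferon-stimulated genes and TLR3 lay under the minimum mean.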

Other observations

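Of the tests below, those of the shared controls, of equal depth for the opposite responses, of the interferon-stimulated genes and of the displacement along the axis were chosen after the values they use had been seen, and so were all gene groups not in the fixed lists. Of 13 measured genes of retinoic acid handling and response, 3 rose with polyI:C, and 2 rose and 5 fell with TGFbeta, and no test was run on such groups. With polyI:C, RARB, a receptor gene that retinoic acid induces, rose by 1.02 ± 0.10 (log2, SE), ALDH1A2 by 1.496 ± 0.21 and the retinal reductase gene DHRS3 by 0.57 ± 0.15. With TGFbeta the same 3 genes fell, by 1.23 ± 0.10, 1.32 ± 0.21 and 1.04 ± 0.15, while CYP26A1, which degrades retinoic acid, and ALDH1A3, which makes it, rose by 2.33 ± 0.41 and 1.81 ± 0.50. Of 12 measured HOX genes, 12 had a log2 change below 0 with TGFbeta, and HOXB1 was among those called (-2.27 ± 0.40). With polyI:C, 9 of 12 were below 0, and HOXB6 was called (-1.59 ± 0.39). Calls ended with 1 library left out for DHRS3 without untreated 2 or 3, polyI:C 1, 2 or 3 (highest adjusted p = 0.148) and HOXB6 without untreated 1, 2 or 3, polyI:C 1, 2 or 3 (highest adjusted p = 0.105) with polyI:C, and for ALDH1A3 without untreated 1 or 3, polyI:C 1 or 3, TGFbeta 1, 2 or 3 (highest adjusted p = 0.120) with TGFbeta.

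Of 13 measured Nodal pathway genes, 6 fell with polyI:C and 6 rose with TGFbeta. NODAL itself fell with polyI:C and had a log2 change of 0.27 ± 0.28 with TGFbeta. LEFTY2 and CER1 rose with TGFbeta and had 0.55 ± 0.63 and 0.10 ± 0.36 with polyI:C. Calls counted here ended with 1 library left out for ACVR1B without untreated 2 or 3, polyI:C 1, 2 or 3 (highest adjusted p = 0.0894) with polyI:C, and for SKIL without untreated 1 or 3, polyI:C 1, 2 or 3, TGFbeta 2 or 3 (highest adjusted p = 0.158) with TGFbeta.

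The first pattern is that 197 of 218 genes called with both treatments moved in opposite directions. Shared untreated libraries push both responses the same way, so simulations of unchanged groups against shared simulated controls can hardly yield opposite calls and decide nothing here. With reads thinned to equal depth 198 opposite calls were found, which argues against the number of reads as the whole cause. With the part along the axis described below taken out of both responses, 153 were found. That part had the same sign in both, with displacements of 0.16 for polyI:C and 0.58 for TGFbeta (standard error 0.33). It pushed both responses the same way, so taking it out was no test of a cause of opposite calls. Whether the treatments push Nodal and TGF-beta signalling in opposite directions was not tested by intervention and stays open.

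The second pattern is the missing rise of the listed interferon-stimulated genes after polyI:C. Among the 19 measured genes the upper 95% limit was under a 2-fold rise for 16, which argues against low levels hiding a rise in these, while IFIT1, IFI6 and DDX60 had limits of 1.33, 1.17 and 1.14 on the log2 scale. The 18 genes under the minimum mean had 126 reads in the untreated and 163 in the polyI:C libraries. The log2 change of their summed normalized counts was 0.14 (95% limits -0.29 to 0.58, Welch). This argues against a 2-fold rise of the sum, though the upper limit was 1.71 and 1.72 without untreated 2 or 3, where 2 untreated libraries are left. The sum leans on its most abundant members, and those with the highest untreated means were lower with polyI:C: IFI27 (7.09 against 8.84 normalized counts) and CMPK2 (3.70 against 8.22). Others were higher, among them IFIT2 and MX1 (3.07 against 1.84), so the sum does not speak for each gene. One by one, 0 reached a mean of 10 in the polyI:C libraries, where IFIT2 came nearest at 9.21 against 3.91 normalized counts, and for single genes low levels cannot be told apart from a missing response because so few reads were counted. An early response that had faded by day 5 stays open, as a single time point was sampled.

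The third pattern is that the TGFbeta response ran along an axis on which libraries of the same group also differed. This axis, the first component of the deviations from group means, held 38.3% of their variance, and gene slopes along it correlated with the TGFbeta response (r = 0.55 across genes, which are not independent) and less with the polyI:C response (0.17). The axis at equal depth correlated with that of the deposited values across genes (r = 0.988), which argues against the number of reads alone as its source. Depth ran only from 10711598 to 13397942 reads, so thinning kept most reads. Untreated 1 and polyI:C 2 had the fewest reads and lowest scores of their groups, and TGFbeta 2 the most reads and highest score. The deepest untreated and polyI:C libraries did not score highest. A property that goes with depth would survive thinning and stays open. From untreated 1 to untreated 2 along the axis, median log2 changes were 0.73 for primitive streak and mesoderm genes, -0.46 for sarcomere genes and -0.26 for cardiac transcription factors. Their TGFbeta medians had the same signs (1.15, -0.43 and -0.20), but those of endoderm (-0.17, then 0.17) and glycolysis genes (0.42, then -0.20) did not. A chance difference between cultures may account for part, also in these lists. The TGFbeta mean was displaced by 1.73 standard errors with libraries taken as unpaired (exact permutation p = 0.2, where the smallest possible is 0.1). With the part along the axis taken out 444 of the 1075 TGFbeta calls were left, among 488 calls in all. By number, each TGFbeta library scored above its untreated one on the axis, at 0.23, 1.03 and 0.47 against -0.57, 0.45 and 0.12. For polyI:C, 979 calls were found after its own part along the axis was taken out, against 1025 before. A slower differentiation under TGFbeta would look like a chance difference between cultures and stays open.

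Splits of the 6 libraries in each comparison number 10, of which the real grouping is 1, too few for a share under 0.05. Every other split also mixes libraries of both groups, so a real difference widens the spread within the mixed groups and leaves few calls. The counts of the other splits are therefore no measure of chance, and nothing is concluded from them. For polyI:C the real grouping called 1025 genes and the highest other split 0 in limma (3032 and 917 at an unadjusted p under 0.05). For TGFbeta the numbers were 1075 and 0 (3227 and 1723), and between treatments 3571 and 0 (5370 and 1014).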
